A study of Mus musculus with 6 samples.

How the data were processed

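Liver RNA from mice kept for 2 weeks on a normal diet (3 libraries) or a zinc-deficient diet (3 libraries) was profiled by RNA sequencing. Per the labels' protocols, 20 ng of total RNA extracted with ISOGEN, a phenol-based reagent, went into each library, made with a low-input cDNA kit. Per the submitters' processing notes, the tools named were Trim Galore, HISAT2 2.2.1 for alignment and featureCounts 2.0.6 for counting, with the mouse genome build mm10. The version of Trim Galore, the gene annotation, the strand setting and the counting of read pairs are not given in the sources used here. The deposited table holds raw counts per gene for 55421 Ensembl identifiers, of which 55240 were matched to a symbol and a position in GENCODE M21, an annotation of the same build (GRCm38). Of the per-sample columns of the table, 0 were left unused.

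Totals lay between 28012096 and 37253164 counts on the normal diet and between 16815305 and 23070001 on the zinc-deficient diet, so depth differed with the diet. Among genes with 1 to 50 counts, between 57.8% and 62.1% of the values in a library were even, an excess over an equal share of odd and even values. Whether both mates of a pair were counted is not given in the sources used here. More genes had 2 counts than 1, for example 1866 against 943 in normal diet replicate 2. Intervals and floors cover counting error at most, since the reads carry no molecular identifiers, and they treat counts as independent. If fragments were counted more than once, the intervals are too narrow. All mitochondrially encoded genes have 0 counts in all 6 libraries, so that list could not be tested. The labels do not say whether the libraries came from separate mice or give the sex of the mice, and p-values measure only the spread between these libraries.

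Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood F test, two-sided, diet as the only term) on the counts as deposited, with Benjamini-Hochberg adjustment and a threshold of 0.05. In this fit 15027 genes were tested. Standard errors of log2 fold changes are the absolute fold change divided by the square root of F. CPM values are counts scaled by the TMM-adjusted library total. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the pooled depth of that group, which is 0.0313 CPM on the normal diet and 0.0510 CPM on the zinc-deficient diet. Where a group had 1 to 3 counts, the ratio is given with an exact 95% counting interval. Tested on simulated data with the means, depths and dispersions of these 15027 genes, the fit called 17 of 100 genes changed 2-fold and 94 of 100 changed 8-fold, with 3 unchanged genes called and 0 calls when no change was simulated. These shares hold for 200 changed genes. With the 3439 genes called in the data the adjusted threshold is less strict, so the 17 may understate the share found there.

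Before the data were examined, 50 gene lists, the rule for named genes and the alternatives were fixed. Lists were tested with limma 3.58.1 camera (TMM log2 CPM, prior count 2, preset correlation 0.01), adjusted over the 49 lists with at least 3 tested members. Named are Kat7, Mt1, Mt2, Slc30a1, Slc39a4, Slc39a10 and Slc39a14; the 10 genes with the largest fitted rise and the 10 with the largest fitted fall among genes past the threshold, with a mean of at least 1 CPM and no overlap between the diets, leaving out predicted-model names; and in each list up to 4 members past the threshold with the smallest p, or 2 members as values where fewer than 2 passed. The sex check used Xist, Ddx3y, Uty, Kdm5d and Eif2s3y. Genes such as the Mup, Sult2a and Cyp2b, Cyp3a and Cyp4a families have near-identical copies, so the division of reads among them is uncertain. Likewise, without a stated strand setting, reads of antisense and overlapping gene models cannot be assigned to a strand with certainty. A few genes named by this rule are not reported here; the list counts include them.

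Sample separation was tested with an exact permutation over the 10 splits of 6 libraries, which cannot give a p under 0.1. Alternatives were other scaling factors, filters, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, an estimated correlation and fry for lists. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the number of genes, so lists pass less easily. After the data were seen, alternatives were added for sex-linked genes and lists, protein-coding genes, GC content and length (a loess offset with a span of 0.3), totals (each library thinned to the shallowest), 2 libraries with transcripts of other tissues, and halved counts.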

Results

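Liver RNA was sequenced from mice after 2 weeks on either a zinc-deficient diet or a normal one, with 3 libraries per diet. The normal diet libraries held 32589449, 37253164 and 28012096 counts in replicates 1, 2 and 3, and the zinc-deficient libraries 17888415, 23070001 and 16815305. Values are given as CPM, the count scaled to a common library size with TMM factors, as mean ± SD over 3 libraries, and fold changes are zinc-deficient relative to normal diet. The adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 15027 genes unless a list test is named.

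The comparison of the diets asks which liver transcripts differ in zinc deficiency, a condition that the series links to the histone acetyltransferase KAT7. The metallothioneins Mt1 and Mt2, which bind zinc, were lower on the zinc-deficient diet, and so was the zinc importer Slc39a4, while the importer Slc39a14 was higher. Transcripts of Kat7 itself did not pass the threshold. All of these differences are also differences between libraries with the transcripts of opposite sexes. The X-linked transcript Xist, which is made from the inactive X chromosome of female cells, stood at 156.6 ± 70.4 CPM on the normal diet and 0.175 ± 0.152 CPM on the zinc-deficient diet (SD, n = 3 each). The Y-linked genes showed the opposite, with Ddx3y at 95.5 ± 30.8 CPM on the zinc-deficient diet and 0.0320 ± 0.0302 CPM on the normal diet. In 6 of 6 libraries the set of sex-linked transcripts went with the diet, so diet and sex cannot be told apart in any comparison here.

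**Figure D1:**
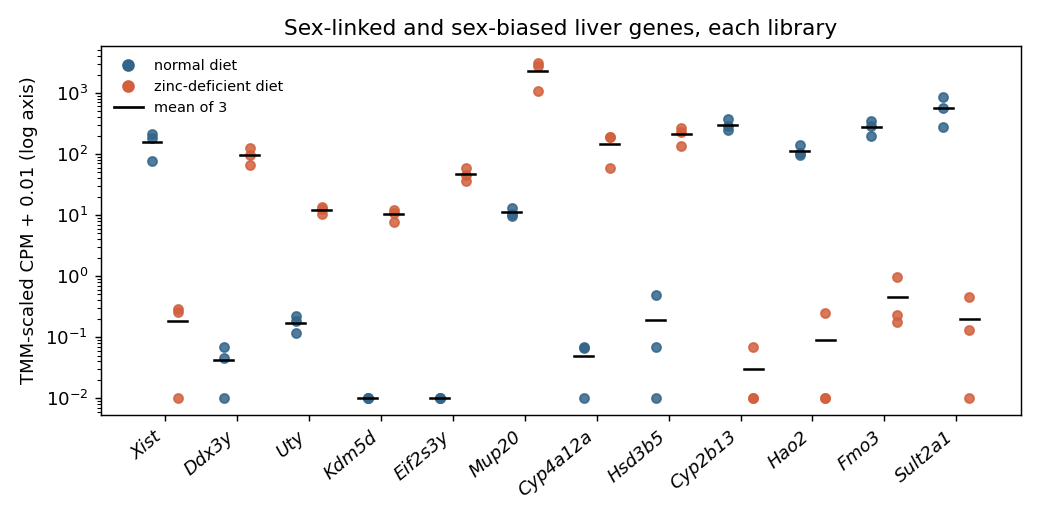
TMM-scaled CPM plus 0.01 on a log axis for 5 sex-linked genes and 7 genes of the sex-biased liver lists; each point is 1 library and each bar the mean of 3. Xist lies between 77.3 and 212 CPM in the normal diet libraries and at most at 0.278 CPM in the zinc-deficient libraries, and the Y-linked genes show the opposite order.

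Of the 15027 genes, 3439 passed the threshold, 1866 higher and 1573 lower on the zinc-deficient diet, and 2927 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 5814 genes. The libraries of the diets did not overlap for 6345 genes, or 42.2%, where chance gives 10%. Libraries of the same diet lay closer together than libraries of different diets, by 59.2 units of distance over the 500 most variable genes (exact permutation test, one-sided, p = 0.1, the smallest that 10 splits allow). The count of genes fell to 1334 without normal diet replicate 2, to 1511 without normal diet replicate 3 and to 2195 without zinc-deficient diet replicate 3. Outside the X and Y chromosomes and the sex-biased lists, 3309 genes were called. Among protein-coding genes 1175 were higher and 1447 lower, whereas of 458 models of the annotation class TEC, which rest on unspliced transcript evidence, 254 were higher and 1 lower.

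Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327) fell from 226.8 ± 89.9 to 14.7 ± 9.82 CPM, a log2 fold change of -3.95 ± 0.49 (SE, adjusted p = 0.000254). Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) fell from 8.04 ± 4.53 to 0.409 ± 0.336 CPM, a log2 fold change of -4.28 ± 0.65 (SE, adjusted p = 0.000949). Both stood lower in each zinc-deficient library than in any normal diet library. Without zinc-deficient diet replicate 1 the log2 fold changes of Mt1 and Mt2 were -4.63 and -5.02. Without zinc-deficient diet replicate 3 they were -3.67 and -3.88, and with the offset for GC content and length -4.36 and -5.08. Of the list of metallothioneins and their regulator Mtf1, 3 members were measured, 2 fell and 1 did not pass, and the same 2 passed when adjusted over the list alone (camera, adjusted p = 0.00906; adjusted p = 0.31 with an estimated correlation). Slc39a4 (ENSMUSG00000063354, chromosome 15, 76612383 to 76617384) fell by 2.52 on the log2 scale, from 124.1 ± 26.1 to 21.6 ± 9.37 CPM (adjusted p = 0.000768). Slc39a14 (ENSMUSG00000022094, chromosome 14, 70303469 to 70351425) rose by 1.66, from 40.4 ± 3.89 to 127.7 ± 35.7 CPM (adjusted p = 0.0025), and did not pass without normal diet replicate 2 and zinc-deficient diet replicate 3 together (adjusted p = 0.057). Of 13 measured SLC39 importers, 2 rose, 7 fell and 4 did not pass, with the same 2 and 7 adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0869). It did pass with the list test fry (adjusted p = 0.00157) and without the same 2 libraries (camera, adjusted p = 0.0402). Slc39a7 (log2 fold change -2.13 ± 0.41 SE) and Slc39a11 (-1.23 ± 0.26 SE) fell, and Slc39a10 stood at 1.31 ± 0.467 and 2.31 ± 1.27 CPM (adjusted p = 0.245). Of 8 SLC30 exporters, 1 fell (Slc30a6, log2 fold change -0.89 ± 0.28 SE) and 7 did not pass, with 0 adjusted over the list alone (camera, adjusted p = 0.873). Slc30a1, which exports zinc across the cell membrane, stood at 16.2 ± 2.22 and 22.2 ± 5.29 CPM (adjusted p = 0.244). These values too carry the opposite sex-linked sets.

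**Figure D2:**
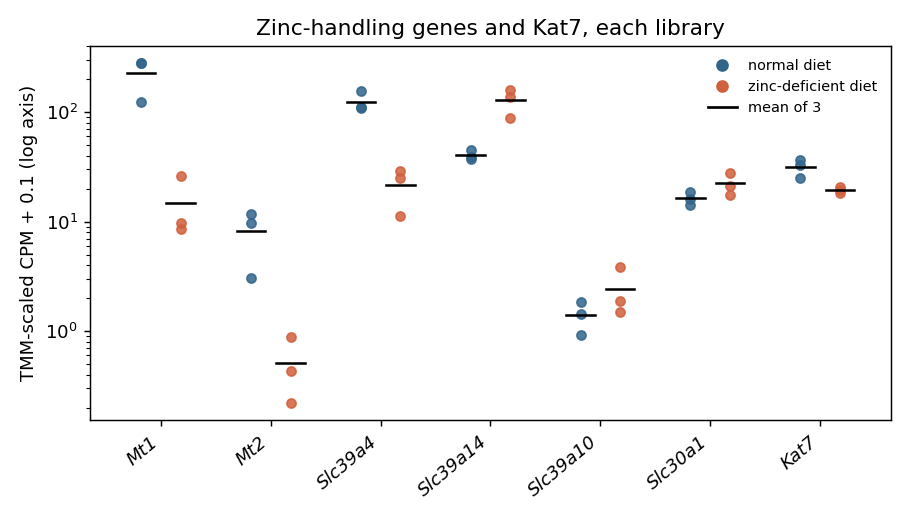
TMM-scaled CPM plus 0.1 on a log axis for 7 genes fixed in advance; each point is 1 library and each bar the mean of 3. Mt1, Mt2, Slc39a4, Slc39a14 and Kat7 do not overlap between the diets, Slc39a10 and Slc30a1 do, and Kat7 did not pass the threshold (adjusted p = 0.0675).

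Kat7 (ENSMUSG00000038909, chromosome 11, 95274259 to 95310246) stood at 31.4 ± 5.8 CPM on the normal diet and 19.3 ± 1.27 CPM on the zinc-deficient diet, a log2 fold change of -0.70 ± 0.26 (SE, adjusted p = 0.0675) that did not pass the threshold, although the libraries did not overlap. With an offset for GC content and length its log2 fold change was -0.365 (adjusted p = 0.202). Of 13 MYST acetyltransferases and partners, 1 rose (Kat6a, log2 fold change 1.16 ± 0.37 SE, adjusted p = 0.0382), 0 fell and 12 did not pass, with 0 adjusted over the list alone (camera, adjusted p = 0.908; the median of -0.10 and the mean of 0.04 differ in sign). Of 10 other histone acetyltransferases, Ep300 rose by 1.37 on the log2 scale (adjusted p = 0.0112) and 9 did not pass, with 1 adjusted over the list alone (camera, adjusted p = 0.782). Of 18 histone deacetylases and sirtuins, 1 rose (Hdac4), 3 fell (Hdac10, Hdac6 and Sirt2) and 14 did not pass, with 1 rising and 5 falling adjusted over the list alone (camera, adjusted p = 0.212). Hdac6 is X-linked.

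Zinc metalloenzymes of liver were measured at 23 genes, of which 2 rose, 7 fell and 14 did not pass, with 3 and 10 adjusted over the list alone (camera, adjusted p = 0.00906; adjusted p = 0.64 with an estimated correlation and 0.081 with fry). The carbonic anhydrase Car2 fell from 23.3 ± 6.08 to 2.68 ± 1.49 CPM (adjusted p = 0.000597), and Sod3, Car14 and Bhmt, the betaine-homocysteine methyltransferase, fell as well. The urea cycle and amino acid catabolism list fell at 13 of 24 genes with 0 rising and 11 not passing, and at 15 adjusted over the list alone (camera, adjusted p = 1.18e-06; adjusted p = 0.18 with an estimated correlation). Ass1, the argininosuccinate synthase of the urea cycle, fell from 3880 ± 295 to 1148 ± 255 CPM (adjusted p = 0.00171), beside Prodh, Oat and Gls2. The one-carbon and methionine cycle fell at 9 of 16 genes, with 0 rising and 7 not passing, and with 1 rising and 9 falling adjusted over the list alone (camera, adjusted p = 0.000559; adjusted p = 0.18 with an estimated correlation). Mat1a, which makes S-adenosylmethionine, fell from 8625 ± 2880 to 2693 ± 352 CPM (adjusted p = 0.00347), beside Sardh, Cth and Mthfd1. Of 30 PPARA targets and fatty acid oxidation genes, 2 rose (Fabp1 and Fgf21), 8 fell, Acadvl among them, and 20 did not pass, with 2 and 9 adjusted over the list alone (camera, adjusted p = 0.000559; adjusted p = 0.65 with an estimated correlation and 0.162 with fry). In that list, 2 members are also in a sex-biased list.

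The drug metabolism list of CAR and PXR, the nuclear receptors for foreign compounds, fell at 20 of 21 genes with 1 not passing, and at 21 adjusted over the list alone (camera, adjusted p = 3.11e-16; adjusted p = 0.32 with an estimated correlation). It shares 2 genes with the fixed female-biased list, and whether its other members differ between the sexes was not tested. Cyp2b10 fell from 82.8 ± 37.2 to 0.0983 ± 0.0336 CPM (adjusted p = 5.56e-07), and Cyp2c37 and Ugt1a1 fell by 3.38 and 3.87 on the log2 scale. The male-biased liver list rose at 18 of 18 genes, also adjusted over the list alone (camera, adjusted p = 8.35e-27; adjusted p = 0.18 with an estimated correlation), and the female-biased list fell at 19 of 20, or 20 adjusted over the list alone (camera, adjusted p = 8.35e-27; adjusted p = 0.18 with an estimated correlation). The median log2 fold change of the female-biased list was -9.29, or -8.71 with genes without counts on the zinc-deficient diet at their bound, and that of the male-biased list was 7.02. These lists hold most of the largest changes. Cyp4a12a rose from 0.0391 ± 0.0339 to 145 ± 73.8 CPM, Mup20, a major urinary protein, by 7.72 on the log2 scale to 2317 ± 1100 CPM, and Hsd3b5 from 0.182 ± 0.266 to 210.5 ± 68.8 CPM. Together with Cyp4a12a and Hsd3b5, the genes Serpina4-ps1, Mup7, Mup-ps17, Cyp4a12b and Mup11 were the autosomal ones among the 10 largest rises. Among the Y-linked genes in that set, Eif2s3y was at least 1540-fold and Kdm5d at least 333-fold higher on the zinc-deficient diet, and the ratio for Ddx3y was 3160 (95% counting interval 1080 to 15300). Cyp2b13 was lower by a ratio of 17900 (95% counting interval 3210 to 706000) and Cyp3a44 by a ratio of 2070 (95% counting interval 372 to 81900). Sult2a3 was at least 1300-fold lower, or 668-fold without normal diet replicate 1 (66.5 ± 56.0 CPM on the normal diet). Sult2a5 was at least 544-fold lower, or 363-fold without that library, and Cyp3a41a at least 544-fold. Sult2a1 (log2 fold change -11.62 ± 0.80 SE), Sult2a2, Sult3a1 and Hao2 fell as well. Myh1, a myosin of skeletal muscle, was at least 171-fold lower, or 37.3-fold without normal diet replicate 2. It stood at 20.6 CPM in normal diet replicate 2 and 2.94 and 0.648 CPM in the others.

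**Figure D3:**
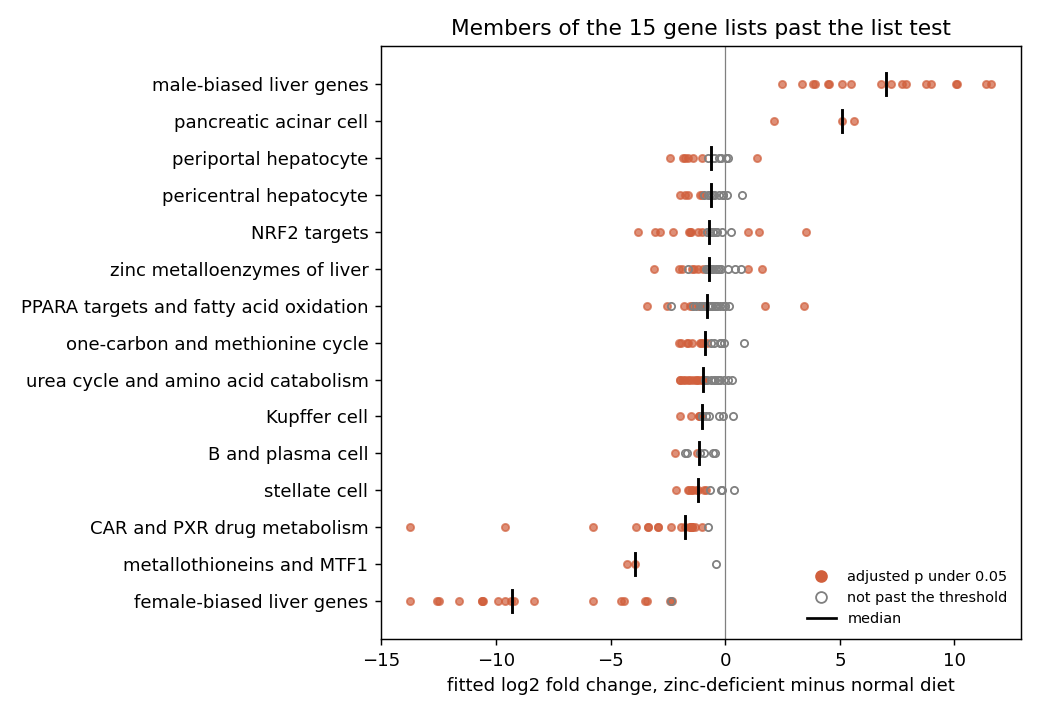
Fitted log2 fold change (zinc-deficient minus normal diet) of each tested member of the 15 lists past the camera test; filled points are genes with adjusted p under 0.05, open points did not pass, and bars are medians. The male-biased median lies at 7.02 and the female-biased median at -9.29, whereas the 24 urea cycle and amino acid genes have a median of -0.95.

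Further metabolic lists did not pass the list test with all 6 libraries. Of 24 cholesterol synthesis genes and SREBP2 targets, 1 rose and 7 fell, among them Insig1 and Lss (2 and 7 adjusted over the list alone, camera adjusted p = 0.212). Of 19 fatty acid synthesis genes, 2 fell, Srebf1 and Dgat2 (the same 2 adjusted over the list alone, camera adjusted p = 0.229). Of 18 lipid droplet and lipase genes, Fitm1 rose and 3 fell, Pparg, Lpl and Lipc (the same adjusted over the list alone, camera adjusted p = 0.763). Gluconeogenesis and fasting had 3 of 14 rising and 2 falling (3 and 3 adjusted over the list alone, camera adjusted p = 0.565), with Gpt and Got1 lower and Lpin1 and Igfbp1 higher. Lpin1 and Igfbp1 overlapped between the diets, as did Insig1 of the cholesterol list and Igfbp3 of the growth hormone and IGF list. Glycolysis had 1 of 14 rising, Pfkfb3, and 4 falling, among them Pfkl and Eno1 (2 and 4 adjusted over the list alone, camera adjusted p = 0.439). Bile acid synthesis and transport had 3 of 19 rising and 6 falling (3 and 7 adjusted over the list alone, camera adjusted p = 0.389). Its transporters Slco1a4 and Abcc3 fell by 4.49 and 2.14 on the log2 scale, and Slco1a1 and Cyp7b1, both in the male-biased list, rose. The growth hormone and IGF axis had 2 of 13 rising and 3 falling, Igfals, Stat5b and Igfbp3 (2 and 4 adjusted over the list alone, camera adjusted p = 0.945, with a positive median and mean and a downward test direction). Of 24 iron and copper genes, 3 rose and 6 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.565). Hamp2, a hepcidin gene, fell by 4.02 on the log2 scale, and Slc40a1, the iron exporter, by 1.96, while Smad7 and Hfe2 rose. The circadian clock had 2 of 19 rising, Clock among them, and 6 falling, among them Cry2, Cry1 and Bhlhe40 (2 and 7 adjusted over the list alone, camera adjusted p = 0.141). With 1 library left out, 3 of these lists passed: cholesterol synthesis without normal diet replicate 2 (camera adjusted p = 0.00564), fatty acid synthesis without zinc-deficient diet replicate 2 (0.0454) and the circadian clock without zinc-deficient diet replicate 3 (0.0313).

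Of the stress lists, the 21 NRF2 targets passed, with 3 rising, 9 falling and 9 not passing (3 and 10 adjusted over the list alone, camera adjusted p = 0.00579; adjusted p = 0.32 with an estimated correlation). The quinone reductase Nqo1 fell from 25.4 ± 2.73 to 3.47 ± 1.57 CPM, Abcc4 and Ugdh fell, and Gstp1 rose by 3.54 on the log2 scale. Gstp1 stood at 2417 CPM in zinc-deficient diet replicate 1 and at 680.5 and 591.9 CPM in the other zinc-deficient libraries. On the normal diet it reached at most 122 CPM. Of 15 heat shock genes, 6 rose and 1 fell (the same counts adjusted over the list alone, camera adjusted p = 0.085), with Hsp90aa1 rising from 19.1 ± 2.99 to 111.5 ± 10.2 CPM, beside Hspa1a, Hspa1b and Hsp90ab1. The heat shock list passed without normal diet replicate 3 (camera adjusted p = 0.0481), without zinc-deficient diet replicate 1 (0.0201) and without zinc-deficient diet replicate 3 (0.0339). The unfolded protein response had 4 of 22 rising, among them Manf, Creld2 and Sdf2l1, and Edem1 falling (4 and 1 adjusted over the list alone, camera adjusted p = 0.275). The integrated stress response had 7 of 17 rising, among them Fgf21 and Ddit4, and 2 falling, Vldlr and Trib3 (8 and 3 adjusted over the list alone, camera adjusted p = 0.439). Fgf21 stood at 23.8 CPM in zinc-deficient diet replicate 1 and at 3.42 and 4.1 CPM in the other zinc-deficient libraries. Ddit4 overlapped between the diets. Glucocorticoid targets had 3 of 14 rising, Gadd45g, Cdkn1a and Ddit4, and Sgk1 falling (3 and 2 adjusted over the list alone, camera adjusted p = 0.36). Cdkn1a stood at 32.2 CPM in zinc-deficient diet replicate 1 and at 4.5 and 3.1 CPM in the other zinc-deficient libraries. Gadd45g was highest in zinc-deficient diet replicate 2. The p53 targets had 3 of 18 rising, among them Cdkn1a and Bax, and 2 falling, Plk2 and Sesn1 (3 and 3 adjusted over the list alone, camera adjusted p = 0.686). Bax too was highest in zinc-deficient diet replicate 1, at 101.8 CPM against 32.8 and 43.6 CPM in the other zinc-deficient libraries. Autophagy had 2 of 24 rising, among them Gabarapl2, and 5 falling, among them Ctsb, Atg7 and Lamp1 (3 and 6 adjusted over the list alone, camera adjusted p = 0.389). Immediate early genes had 2 of 16 rising, Gadd45g and Fos, and 2 falling, Nr4a1 and Junb (the same counts adjusted over the list alone, camera adjusted p = 0.945, with median and mean of opposite sign).

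Among immune and matrix lists, the acute phase response had 5 of 27 rising, among them Crp, Saa1 and Lrg1, and 2 falling, Hamp2 among them (8 and 5 adjusted over the list alone, camera adjusted p = 0.497). Crp and Saa1 stood at 276.7 and 172 CPM in zinc-deficient diet replicate 1, against at most 127.1 and 55.5 CPM in the other zinc-deficient libraries. Complement and coagulation had 6 of 31 rising, among them C6, which is also in the male-biased list, C8a and C9, and 6 falling, Cfb among them (6 and 11 adjusted over the list alone, camera adjusted p = 0.389). Of 27 interferon-stimulated genes, 4 fell, Gbp3, Gbp2, Usp18 and Ifih1 (3 adjusted over the list alone, camera adjusted p = 0.095). Of 15 cytokine and chemokine genes, 2 fell, Icam1 and Cxcl13 (the same 2 adjusted over the list alone, camera adjusted p = 0.66). Of 20 cell cycle genes, 2 fell, Ccnd1 and Mcm6 (the same 2 adjusted over the list alone, camera adjusted p = 0.0927). Fibrosis and matrix genes had Ccn2 rising and Col3a1 and Col1a1 falling of 16 (the same adjusted over the list alone, camera adjusted p = 0.143). The interferon list passed with fry (adjusted p = 0.0222) and without normal diet replicate 2 (camera adjusted p = 0.0329). Without normal diet replicate 3 or zinc-deficient diet replicate 1, the cell cycle list (0.0189 and 0.0305) and the fibrosis and matrix list (0.0275 and 0.0377) passed.

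Of 13 tested lists of liver zone and cell type markers, 6 passed, and 0 with an estimated correlation. These lists too carry the opposite sex-linked sets. The periportal list shares genes with the urea cycle and amino acid catabolism list, Ass1 and Gls2 among them. The pericentral list shares Oat with that list and Cyp2c29 with the drug metabolism list. The calls of the zone lists are therefore not independent of those lists. Pericentral hepatocyte markers fell at 5 of 16 genes, among them Oat, Cyp2c29, Tbx3 and Lhpp (5 adjusted over the list alone, camera adjusted p = 0.00757; adjusted p = 0.55 with an estimated correlation). Periportal markers had 1 of 14 rising and 6 falling, among them Aldh1b1, Ass1, Gls2 and Ctsc (1 and 7 adjusted over the list alone, camera adjusted p = 0.00327; adjusted p = 0.21 with an estimated correlation). Kupffer cell markers fell at 6 of 14 genes, among them Slc40a1, Adgre1, Cd163 and Vsig4 (7 adjusted over the list alone, camera adjusted p = 0.00168; adjusted p = 0.64 with an estimated correlation and 0.116 with fry). Stellate cell markers fell at 9 of 13 genes, among them Ecm1, Lrat, Ngfr and Pdgfrb (9 adjusted over the list alone, camera adjusted p = 0.00168; adjusted p = 0.45 with an estimated correlation). B and plasma cell markers fell at 2 of 8 genes, Ighm and Cd79a (4 adjusted over the list alone, camera adjusted p = 0.0264; adjusted p = 0.55 with an estimated correlation and 0.068 with fry), and the list did not pass without normal diet replicate 1 (camera adjusted p = 0.105) or with a filter at 1 CPM (0.19). Of 15 general hepatocyte markers, Apoa1 rose and 3 fell, among them Cps1 and Trf (the same counts adjusted over the list alone, camera adjusted p = 0.926). The sinusoidal endothelial list had 0 of 14 passing (camera adjusted p = 0.904), with Oit3 at adjusted p = 0.0834 and Lyve1 at 0.132. Cholangiocyte markers had 1 of 9 falling, Prom1 (camera adjusted p = 0.143), and T and NK cell markers 1 of 7, Trac (camera adjusted p = 0.26). Without zinc-deficient diet replicate 1 both lists passed (0.0184 and 0.0305). Alas2 rose among 6 erythroid genes (camera adjusted p = 0.907). The neutrophil and monocyte list (3 tested, camera adjusted p = 0.56) and the adipocyte list (5 tested, camera adjusted p = 0.689) had 0 passing. The pancreatic acinar list rose at 3 of 3 tested genes (3 adjusted over the list alone, camera adjusted p = 0.0276; adjusted p = 0.55 with an estimated correlation and 0.0767 with fry), and it did not pass without zinc-deficient diet replicate 3 (camera adjusted p = 0.0615), with voom weights (0.055) or with the offset for GC content and length (0.0519). In that library the tested genes Cela2a and Cpb1 stood at 39.98 and 14.51 CPM, against at most 0.66 and 0.833 CPM in the other libraries. Cela1 was higher in each zinc-deficient library, at 41.7, 28.0 and 48.7 CPM against at most 11.4 CPM on the normal diet (adjusted p = 0.000791). Without zinc-deficient diet replicate 3 it still passed (adjusted p = 0.0032), whereas Cpb1 and Cela2a did not (0.132 and 0.348).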

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

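Settings chosen after the data were seen are the sex-linked, protein-coding, GC and length, thinned, halved and 2-library ones. Under the scalings, filters and tools the count of 3439 genes stayed between 3200 and 4291, and no scaling moved the median of all genes by over 0.1 (log2). Leaving out each library gave 1334 to 3959 genes, 711 to 2221 higher and 623 to 1738 lower, and 1334 to 3659 at 2-fold. Library number, equal in each fit, does not explain this range. Without normal diet replicate 2, 92.3% of the 2-fold genes kept size and direction (86.5% to 98.4% over these fits). The genes were chosen partly on these libraries, which favours high shares. Of the 3439 genes, 37.3% remained called without normal diet replicate 2 and 86.1% without zinc-deficient diet replicate 2, the lowest and highest shares. Without normal diet replicate 2 and zinc-deficient diet replicate 3 together 1004 genes passed, 605 higher and 399 lower, and 1004 at 2-fold. Among protein-coding genes alone 1175 were higher, fewer genes being counted. Offsetting GC content and length gave 3719 genes, thinning 3228 and halving 3390. With the replicate number as a block 3654 genes passed. Same-numbered libraries deviated with correlations of 0.091, -0.033 and 0.052, and not every library correlates best with its own number. These values give no sign of pairing, but with deviations taken from the means of 3 libraries they cannot exclude it. The 15 lists kept their call with the block, and the zinc importer list passed as well (adjusted p = 0.0466). With an estimated correlation 0 of the 15 lists passed (smallest adjusted p = 0.18). The estimates for the urea cycle, one-carbon, periportal and metallothionein lists were -0.019, -0.007, 0 and -0.148, below the preset 0.01. They argue against correlated members as what cost those lists their call. The other lists of the 15 had estimates above the preset, up to 0.677 for acinar cells. That setting also has fewer degrees of freedom, which can cost a list its call without correlated members. For the lists above the preset these reasons were not told apart, and the loss of a call is not evidence against a list. With fry 12 lists passed, 10 of the 15 and the zinc importer and interferon lists, while zinc metalloenzymes, PPARA targets, Kupffer cells, B and plasma cells and acinar cells did not. Leaving out each library, 14 to 20 lists passed, and 18 without the 2 libraries, 13 of the 15 (B and plasma cells at 0.0719 and acinar cells at 0.0752 did not) and the zinc importer (0.0402), cholesterol (0.0194), heat shock (0.019), interferon (0.0392) and circadian clock (0.0185) lists. The acinar list was not tested with the filter at 1 CPM. Sample separation ranged from 53.6 to 63.0 without each library.

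Directions turned only for lists whose test did not pass in either setting. The values are adjusted p-values and the cause was not tested. With fry, they were 0.84 for immediate early genes and 0.455 for hepatocyte markers. With a CPM filter, it was 0.979 for the growth hormone axis and immediate early genes, and with the block 0.912 for the growth hormone axis. With the GC and length offset they were 0.809 (lipid droplet, immediate early), 0.995 (glycolysis, hepatocyte), 0.904 (growth hormone), 0.599 (sinusoidal endothelial) and 0.723 (erythroid). Without the 2 libraries they were 0.863 (MYST), 0.982 (p53), 0.133 (immediate early), 0.946 (sinusoidal endothelial) and 0.414 (erythroid). Leaving out each library gave ranges of 0.59 to 0.985 (zinc exporters), 0.578 to 0.962 (MYST), 0.465 to 0.989 (other acetyltransferases), 0.407 to 0.993 (lipid droplet), 0.774 to 0.939 (growth hormone), 0.216 to 0.867 (immediate early), 0.807 to 0.962 (hepatocyte), 0.494 to 0.98 (sinusoidal endothelial) and 0.216 to 0.962 (erythroid). Of the named genes over all settings, 0 values reversed, 271 lost and 5 gained the threshold. The 17 of 100 simulated 2-fold calls had 200 genes changed.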

Other observations

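Gene families chosen after their values were seen added a further group. Of 76 cytosolic ribosomal protein genes, 50 rose and 0 fell on the zinc-deficient diet, with a median log2 fold change of 1.43 ± 0.52 (SD across genes). With the offset for GC content and length, 28 rose and the median was 1.01. Of 75 subunits of the respiratory complexes, 14 rose and 2 fell (median 0.91), and with the offset 7 rose and 3 fell (median 0.37). Of 38 proteasome subunits, 2 rose and 1 fell (median 0.32), and with the offset 8 rose and 1 fell (median 0.07), and of 8 histone genes 2 rose and 0 fell (median 0.69, or 0.3 with the offset). Of 22 major urinary protein genes, 21 rose.

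The tests of total counts, of GC content and length, of single libraries with other tissues, of muscle transcripts without normal diet replicate 2, of genomic DNA, of unspliced transcripts and of short models were fixed before their results were seen. The tests of splits, of sex, of a wrong label, of muscle in 1 library, of acinar transcripts, of DNA by length and of 3 libraries left out were chosen after. For the 3439 genes that differed between the diets, 1 of the 10 splits of the 6 libraries into 3 and 3, the diets themselves, gave as many genes, and the highest of the other splits gave 0, although 10 splits are too few for a share under 0.05. Each other split put libraries of both diets in each set. That widens the spread within the sets, so the 0 calls do not show what chance gives. The difference in total counts does not account for most of them, since thinning each library to the shallowest total left 93.9% as many genes, and with the offset for GC content and length 78.6% of the called genes remained called. Without the 2 libraries with transcripts of other tissues, 922 of the 3439 genes (26.8%) remained called, with fewer libraries tested. Most fold changes did not rest on those 2 libraries alone. Of the genes called at 2-fold or more, 89.1% kept a change of at least 2-fold in the same direction without them. The libraries that remained had also served to choose these genes, which favours a high share. Normal diet replicate 1, which also held muscle transcripts, stayed in that comparison. Without it as well 90.8% kept such a change (pooled CPM, 1 normal diet library, no test), against 86.6% without the 2 alone on that scale. What stays open is sex: the 3309 genes called outside the X and Y chromosomes and the sex-biased lists cannot be told apart from a difference between female and male liver, because no library of the other sex on either diet is among the 6.

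The sorting of the sex-linked transcripts with the diet is the pattern a follow-up would turn to first. The libraries are not all from mice of 1 sex, since 6 of 6 carry the set opposite to that of the other diet. No single library stands apart from its group, with 0 libraries carrying the set of the other diet. Both counts restate the sorting and do not test its cause. A wrong label among libraries with the same set would not show in them. A difference in the sex of the mice is consistent with the fixed lists, in which 97.4% of the tested sex-biased genes passed in the direction of their name. Whether diet also changed these genes within a sex was not tested, since the design holds no such contrast, and neither was an exchange of whole groups of libraries with other material, under which the fold changes here would not be those of the diets.

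Unspliced, intronic and antisense models rose on the zinc-deficient diet: of 458 models of the annotation class TEC, 254 rose and 1 fell (median log2 fold change 2.04), and of 323 antisense models 102 rose and 6 fell. Genomic DNA may contribute, since pooled CPM of 1468 olfactory and vomeronasal receptor genes was 3.76 times as high on the zinc-deficient diet, with 23.3 ± 2.66 and 87.6 ± 45.2 CPM (SD, n = 3). In zinc-deficient diet replicates 1, 2 and 3 the receptor genes stood at 136, 46 and 81.2 CPM, against at most 25.7 CPM on the normal diet. The 458 TEC models varied less between those replicates, at 1460, 1260 and 1460 CPM. Genomic DNA would not account for the whole rise by length alone, because the rise per kb over all 3214 TEC models was 14.1 times that over the receptor genes. Unspliced transcripts are a candidate explanation: TEC models within protein-coding genes rose by 0.96 more (median log2) than the others, 2.27 ± 1.20 against 1.32 ± 1.51 (SD across models). Short models do not carry it, as 81.1% of the higher TEC models remained called with the length offset, and diet and sex stay open as untested causes.

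Muscle transcripts were highest in normal diet replicate 2 for 10 of 10 genes of a list chosen after the data were seen, with Acta1 at 314 CPM there and 41.4 and 3.78 CPM in the other normal diet libraries. Without that library their median log2 fold change was -4.01, a value carried by normal diet replicate 1, since it was -4.67 against that library alone and -1.7 against normal diet replicate 3 alone. In replicate 3, 3 of the 10 genes, Ckm, Mylpf and Casq1, stood no higher than in the highest zinc-deficient library. All 13 acinar genes were highest in zinc-deficient diet replicate 3, and without it 3 of 13 kept a log2 fold change of at least 1.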
